A study of Dugesia japonica with 15 samples.

How the data were processed

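Polyadenylated RNA from groups of *Dugesia japonica* animals was sequenced in 15 libraries, per the labels' protocols: Trizol extraction, capture on oligo-dT beads, cDNA synthesis, adapter ligation, PCR and paired-end sequencing on an Illumina instrument. The libraries fall into 4 groups by their labels: control RNAi intact (n = 4), DjTcf4 RNAi intact (n = 4), control RNAi at 5 dpa (n = 4) and DjTcf4 RNAi at 5 dpa (n = 3, replicates 1, 3 and 4). The labels do not say whether replicates came from separate groups of animals, so p-values measure the spread between these samples, which may in part be technical. No 2 replicates agreed within sampling noise: chi-square divided by its degrees of freedom lay between 3.64 and 73.5 over all replicate pairs.

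The deposited table holds expected counts per gene, estimated counts that need not be whole; 8.23% of its values have a fractional part. The submitters' processing notes name Bowtie2, HISAT2, RSEM and DESeq2, with neither the role nor the version of any. RSEM gives fractional counts where reads match several genes or transcripts, but the notes do not state that it made this table. The genome build and annotation are not given in the sources used here. Fractional values occurred in at least 1 library for 3242 of the tested genes (19.0%), and the counts of these genes are uncertain if reads were divided between similar sequences. Values were rounded to whole numbers before testing. The table has 38792 rows, of which 10466 were at 0 in every library. No columns were left without a sample.

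Row IDs are not paired with gene names in the deposited table, and no reference was used here. The gene lists and cell type markers fixed before the data were examined were therefore not tested, and the level of DjTcf4 itself was not analysed, so the knockdown has no check here. Genes are given by ID, and any of them, DJKW.51 included, could be the row of DjTcf4. The rule fixed before the data were examined allows, without names, at most 2 IDs each way among genes called in the same direction in both RNAi comparisons with a mean of at least 5 CPM; 1 gene, DJKW.51, met it. DJKW.14394 and DJKW.832 were chosen after their values were seen. Values of other genes are given without an ID.

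Total counts ranged from 8136366 to 12224216 per library. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 17094 genes (44.1%). Library sizes were scaled with TMM. Tests used edgeR 4.0.16 in R 4.3.3: 1 quasi-likelihood model with robust dispersions over all 15 libraries and 1 coefficient per group, 5 contrasts, and Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call, with counts also given at a fold change of at least 2. Standard errors of log2 fold changes are approximate, computed as the absolute log2 fold change divided by the square root of F. CPM values, counts divided by the effective library size, are scaled with the same factors. The biological coefficient of variation was 0.213, and 0.154 without DjTcf4 RNAi intact replicate 2.

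A position was computed per library as the mean log2 CPM (prior count 2) of the genes called higher, or lower, at 5 dpa in control animals, placed on a scale with the control intact mean at 0 and the control 5 dpa mean at 1. Positions of RNAi and control libraries were compared with two-sided exact permutation tests. The response of these genes to RNAi at 5 dpa was computed with shared controls, with the 4 control 5 dpa libraries split into 2 and 2, and in 20 simulated sets with no RNAi effect. The 2 RNAi comparisons share no library with each other, nor do the 2 comparisons of 5 dpa with intact animals.

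The steps were tested on simulated counts drawn from the real means and spreads with 200 genes changed by known folds. At 1.5-, 2- and 4-fold, calls recovered 13.4%, 47.8% and 86.4% of the changed genes for RNAi in intact animals (16853 genes tested), 8.96%, 50.7% and 87.9% for RNAi at 5 dpa (16906 genes) and 8.96%, 46.3% and 87.9% for 5 dpa against intact controls (16847 genes). Of the calls, 9.26%, 9.26% and 7.77% were genes simulated as unchanged, above the nominal share.

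Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), a fit to the compared groups alone, the fold threshold and leaving out each library. Fits without DjTcf4 RNAi intact replicate 2 for comparisons that do not include it, the positions in intact animals without that library, and the correlation of the 2 responses to amputation, were added after the data were seen. All refits of regrouped libraries enumerated 35 splits, or drew 40 for the interaction.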

Results

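Gene expression was measured by mRNA sequencing in the freshwater planarian *Dugesia japonica*, a flatworm that regrows missing body parts, after RNA interference (RNAi) against DjTcf4 or control RNAi. Some proteins named TCF are transcription factors that partner with β-catenin in Wnt signalling. Whether DjTcf4 is one of them was not examined here. Intact animals were compared with trunk fragments at 5 days post amputation (5 dpa), in a series concerned with the timing of differentiation during regeneration. There were 4 control intact, 4 DjTcf4 RNAi intact, 4 control 5 dpa and 3 DjTcf4 RNAi 5 dpa libraries. Total counts per library ranged from 8955897 to 11323359, from 9148426 to 12224216, from 8136366 to 11575613 and from 9580929 to 11808084 in these groups.

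Libraries separated mainly by amputation, with 51.8% of the variance on the first principal component and 10.1% on the next. DjTcf4 RNAi intact replicate 2 lay among the 5 dpa libraries on the first component and apart from all others on the next. Its score on the first component was 55.9, against -69.2 to -31.4 in the other 7 intact libraries and 15.6 to 56.0 at 5 dpa. Its score on the next component was 63.0, against -32.3 to 2.16 at 5 dpa and at most 19.5 in any other library. On the scale from the control intact mean (0) to the control 5 dpa mean (1), it stood at 1.04 for genes lower at 5 dpa and at 0.717 for genes higher at 5 dpa, where the lowest 5 dpa library stood at 0.914. Its median correlation across genes was 0.962 with the 5 dpa libraries, whose lowest correlation with each other was 0.966, and 0.919 with the other intact libraries. The other intact libraries had a median correlation of 0.945 with the 5 dpa libraries. Their highest was 0.970, against a highest of 0.968 for this library. Counts are therefore also given without this library, which for RNAi at 5 dpa and for regeneration in control was a choice made after the data were seen.

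**Figure D1:**
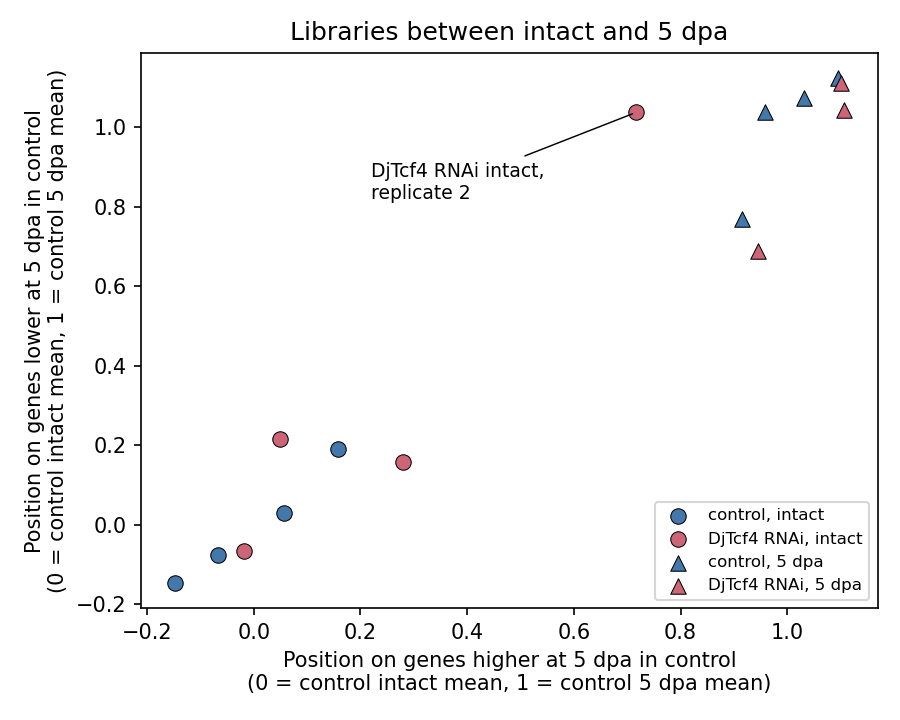
Position of each of the 15 libraries on genes called higher (x axis) and lower (y axis) at 5 dpa in control animals, where 0 is the control intact mean and 1 the control 5 dpa mean (no unit). Each point is a library; DjTcf4 RNAi intact replicate 2 sits at 0.717 and 1.04, away from the other intact libraries.

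The first comparison asked which genes differed between DjTcf4 RNAi and control RNAi in intact animals. DJKW.51 fell from 53.3 ± 4.35 CPM in control to 17.4 ± 1.12 CPM with DjTcf4 RNAi (SD, n = 4 each), a log2 fold change of -1.61 (SE 0.145, edgeR quasi-likelihood adjusted p = 3.84e-05). The other called gene fell from 55.6 ± 4.84 to 34.0 ± 2.89 CPM (log2 fold change -0.71, SE 0.108, edgeR adjusted p = 0.0332). Of 17094 genes tested with edgeR, 2 were lower and 0 higher, and 1199 had an unadjusted p under 0.05, against 855 expected with no effect. DESeq2 called 30 lower and 6 higher, and limma-voom 39 lower and 4 higher. Genes with a count numbered 22007 to 22878 in control replicate 1 and RNAi replicates 1, 2 and 4, and 20699 to 21396 in the other 4 intact libraries, so this measure went partly with RNAi.

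Without DjTcf4 RNAi intact replicate 2, 23 genes were called lower and 0 higher with RNAi in intact animals, the 2 genes above among them. Their log2 fold changes lay between -1.58 and -0.41. The unadjusted p was under 0.05 for 914 genes in that fit.

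**Figure D2:**
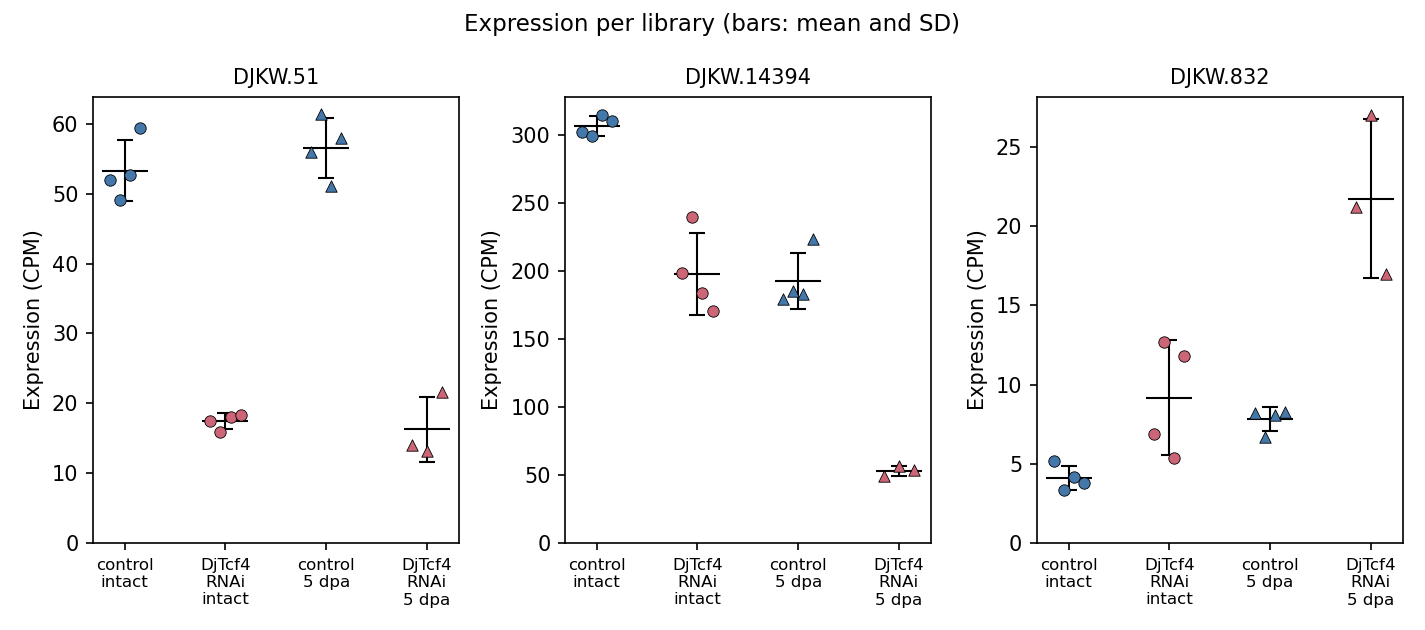
Expression in CPM (y axis, linear from 0) of DJKW.51, DJKW.14394 and DJKW.832 in the 4 groups; points are libraries and bars the mean and SD. DJKW.51 averaged 17.4 and 16.3 CPM with DjTcf4 RNAi against 53.3 and 56.6 CPM in control, intact and at 5 dpa.

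The comparison at 5 dpa asked the same of regenerating trunk fragments. DJKW.51 again fell, from 56.6 ± 4.29 CPM in control (n = 4) to 16.3 ± 4.64 CPM with DjTcf4 RNAi (SD, n = 3), a log2 fold change of -1.79 (SE 0.162, edgeR adjusted p = 1.95e-05). Amputation left a log2 difference of 0.09 in its level in control animals (SE 0.139, edgeR adjusted p = 0.672). DJKW.14394 fell from 193 ± 20.5 to 53.1 ± 3.59 CPM (log2 fold change -1.86, SE 0.127, edgeR adjusted p = 4.76e-07). The most abundant of the called genes fell from 1486 ± 150 to 679 ± 104 CPM (log2 fold change -1.13, SE 0.139, edgeR adjusted p = 0.00101); its counts were fractional in all 15 libraries, so its level is uncertain if reads were divided between similar sequences. Another gene fell from 120 ± 15.2 to 38.1 ± 4.06 CPM (log2 fold change -1.66, SE 0.161, edgeR adjusted p = 4.03e-05). DJKW.832 rose from 7.81 ± 0.755 to 21.7 ± 5.02 CPM (log2 fold change 1.47, SE 0.257, edgeR adjusted p = 0.0465), a call that ended in 11 of 19 alternatives (adjusted p from 0.000102 to 0.256), while its log2 fold change stayed between 1.29 and 1.62.

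At 5 dpa, 7 genes were lower and 1 was higher with DjTcf4 RNAi. The log2 fold changes of the 7 lay between -2.11 and -1.002, and 2 of them had fractional counts. The unadjusted p was under 0.05 for 553 genes, fewer than the 855 expected. DESeq2 called 36 lower and 4 higher, and limma-voom 47 lower and 9 higher. Of the 7 lower genes, 6 were also called lower at 5 dpa than in intact controls. Without DjTcf4 RNAi intact replicate 2, which enters the pooled spread, 25 genes were lower and 3 higher, with all 8 genes above among them. Of those 25 genes, 22 were lower at 5 dpa than in intact controls where 5.68 were expected (one-sided exact hypergeometric p = 7.26e-12), and 1 was higher. Their median log2 fold change was -0.98 with RNAi at 5 dpa and -0.77 after amputation in control. These comparisons share the control 5 dpa libraries, whose chance values push the responses in opposite directions. With the controls split, also without that replicate, 6 to 33 genes were lower with RNAi. Of these, 63.6% to 93.9% were also lower after amputation, 3.67 to 5.57 times the number expected. The numbers expected are for independent lists, while these lists come from 1 fit with a shared spread per gene.

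The calls of the RNAi comparisons depended on single libraries. In intact animals 1 gene remained called without any of control replicates 2, 3 and 4 or DjTcf4 RNAi replicates 1, 3 and 4, and at 5 dpa 4, 5 and 4 genes were called without control replicate 3, control replicate 4 and DjTcf4 RNAi replicate 1. DJKW.51 was called in both comparisons in each of 19 alternatives.

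The responses to RNAi in intact animals and at 5 dpa, which share no library, had a correlation of 0.027 across genes (Spearman 0.038), and 0.103 without DjTcf4 RNAi intact replicate 2; genes are not independent replicates. DJKW.51 was the 1 gene lower in both, where 0.00082 were expected from the sizes of independent lists. The row of DjTcf4 is not known, so DJKW.51 could be the knockdown target itself. The 7 genes lower at 5 dpa all had a log2 fold change below 0 in intact animals. Without that replicate, 9 genes were lower in both, where 0.034 were expected (one-sided exact hypergeometric p = 5.27e-21). In that setting, 24 of the 25 genes lower at 5 dpa were below 0 in intact animals. The lists come from 1 fit with a shared spread per gene, so the expected numbers may be too low and this p too small.

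**Figure D3:**
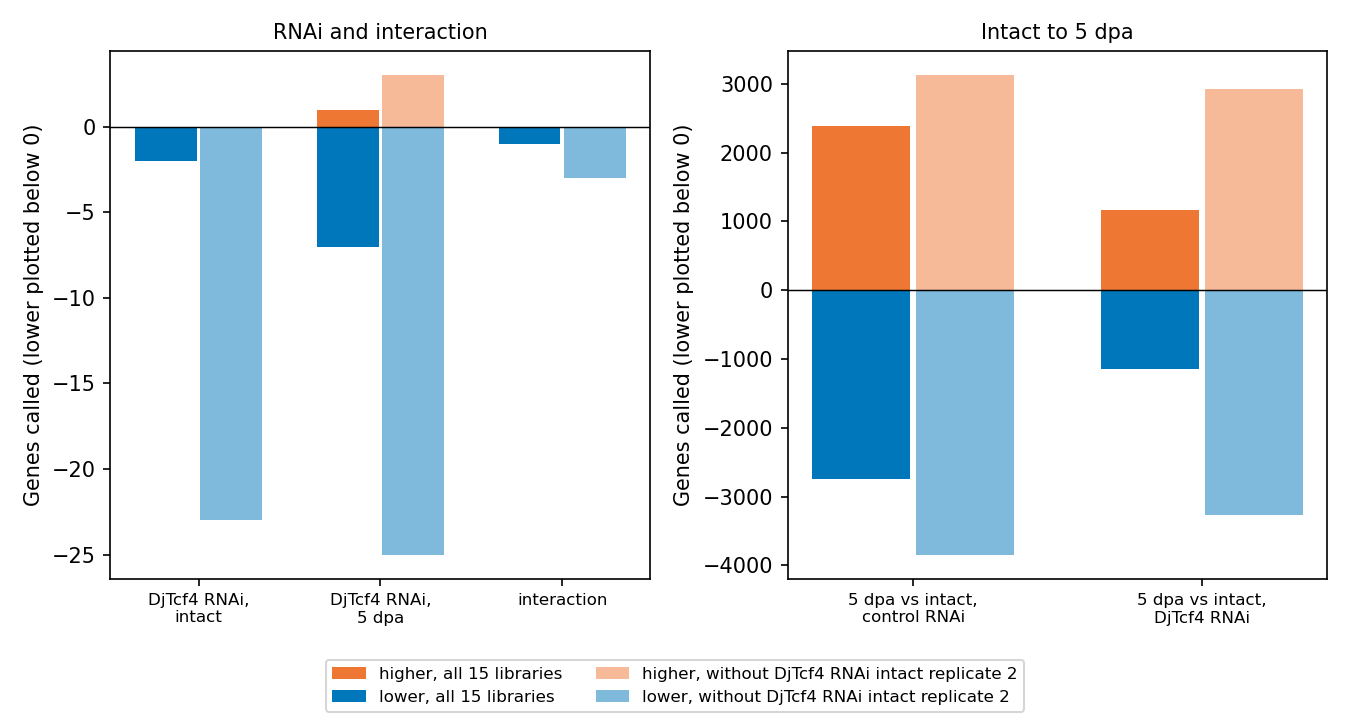
Number of genes called higher (above 0) and lower (below 0) at an adjusted p under 0.05 in edgeR, for the RNAi comparisons and interaction (left) and for 5 dpa against intact (right), on linear axes of different scale. Dark bars use all 15 libraries and pale bars leave out DjTcf4 RNAi intact replicate 2, which raised the lower calls with RNAi from 2 to 23 in intact animals and from 7 to 25 at 5 dpa.

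In control animals, the comparison of 5 dpa trunk fragments with intact animals gave the change after amputation, together with any difference between a trunk and a whole animal. Of 17094 genes, 2391 were higher and 2751 lower at 5 dpa (edgeR, adjusted p under 0.05). Changes of at least 2-fold were mostly falls, with 1724 lower and 191 higher genes. The median log2 fold change was 0.58 in the genes that rose and -1.23 in those that fell. In the 4274 genes with the highest mean expression (median 87.8 CPM), 1199 rose and 600 fell, and 19 rose and 201 fell at least 2-fold; in the 1000 most abundant, 9 rose and 42 fell at least 2-fold. In the 4274 with the lowest (median 1.42 CPM), 125 rose and 603 fell. DJKW.14394 fell from 307 ± 7.17 to 193 ± 20.5 CPM (SD, n = 4 each; log2 fold change -0.67, SE 0.110, edgeR adjusted p = 0.000969), and DJKW.832 rose from 4.11 ± 0.784 to 7.81 ± 0.755 CPM (log2 fold change 0.92, SE 0.258, edgeR adjusted p = 0.0145). The count was 3208 without control intact replicate 4, 2950 without control 5 dpa replicate 1 and 6965 without DjTcf4 RNAi intact replicate 2.

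In DjTcf4 RNAi animals, 1164 genes were higher and 1141 lower at 5 dpa than in intact animals, with 149 and 630 at least 2-fold. Fitted to these 2 groups alone, edgeR called 265 higher and 310 lower, and limma-voom on all libraries called 3434 higher and 3528 lower. Of the genes called with all libraries in edgeR, 947 were also higher in control, where 163 were expected from the sizes of independent lists, and 804 were also lower, where 184 were expected. No gene was called in opposite directions with all libraries. Of the 5142 genes called in control, 98.5% had the same sign with DjTcf4 RNAi. The fold changes in control and RNAi animals correlated at 0.764 across genes (Spearman 0.770), with a least-squares slope of 0.626. Noise in the control fold changes lowers such a slope, so it does not by itself show a weaker response with RNAi. Without DjTcf4 RNAi intact replicate 2, 2930 genes were higher and 3266 lower, 1 gene was called in opposite directions, the correlation was 0.831 and the slope 0.782. In that setting, genes that rose in control had a median log2 fold change of 0.50 in control and 0.51 with RNAi. Genes that fell in control had medians of -1.02 and -0.88. The number of genes called with RNAi was 1533, 1487, 1048 and 1130 without intact replicates 1 and 3 and 5 dpa replicates 3 and 4.

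**Figure D4:**
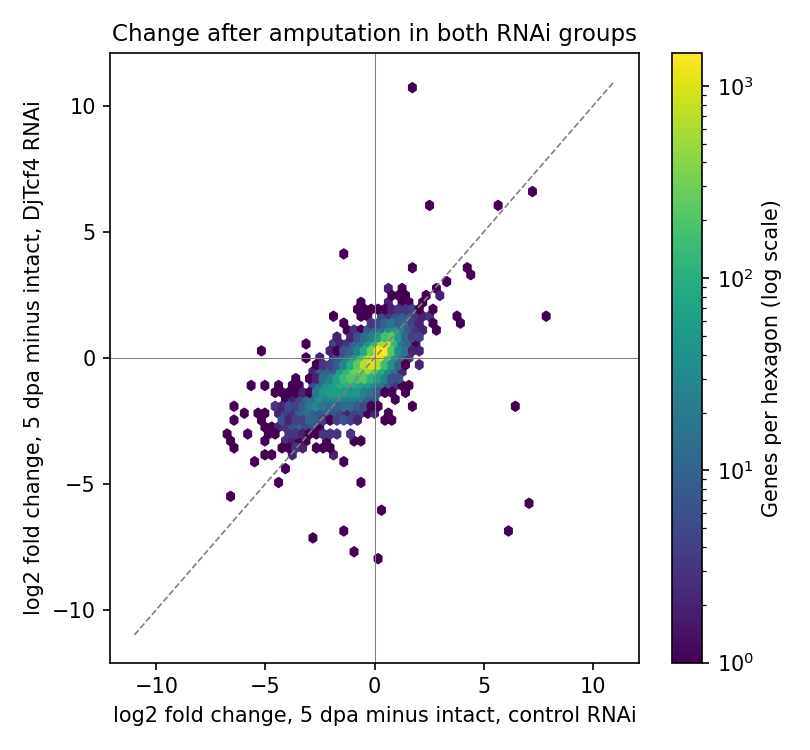
Log2 fold change from intact to 5 dpa of each of the 17094 tested genes in control RNAi (x axis) and DjTcf4 RNAi (y axis); colour gives the number of genes per hexagon on a log scale and the dashed line marks equal change. The changes correlate at 0.764 across genes with a least-squares slope of 0.626, less steep than the dashed line. Noise in the control fold changes lowers such a slope, so it does not by itself show a weaker response with RNAi.

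The interaction asked whether the change after amputation differed between RNAi groups. The 1 gene called was DJKW.14394, which was at 198 ± 30.1 CPM in DjTcf4 RNAi intact animals, a log2 fold change of -0.63 from control (SE 0.110, edgeR adjusted p = 0.0951); without DjTcf4 RNAi intact replicate 2 this was a call, with a log2 fold change of -0.74 (edgeR adjusted p = 0.000893). Its fall with RNAi at 5 dpa exceeded that in intact animals by a log2 fold change of -1.23 (SE 0.165, edgeR adjusted p = 0.0125). That call ended in 7 of 18 alternatives (adjusted p from 1.79e-08 to 0.164), among them leaving out any of control intact replicates 1, 2 and 3 or DjTcf4 RNAi 5 dpa replicates 1, 3 and 4, while its log2 fold change stayed between -1.28 and -1.10 in all 18. No gene had a higher interaction in edgeR, with 593 genes in all at an unadjusted p under 0.05, while DESeq2 called 1 higher and 8 lower and limma-voom 0 higher and 4 lower. Without DjTcf4 RNAi intact replicate 2, 3 genes were called, with log2 differences from -1.10 to -0.89, and all 3 were lower with RNAi at 5 dpa.

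The genes that changed after amputation in control were then followed as sets with RNAi at 5 dpa. The median log2 fold change with RNAi was 0.029 for the 2391 genes that rose and 0.058 for the 2751 that fell. Sets with no RNAi effect, simulated with the same shared controls, gave -0.062 (-0.072 to -0.051) and 0.065 (0.051 to 0.079). Genes were drawn independently in these sets, while real libraries can shift many genes together. The simulated ranges are therefore too narrow to judge the real values by. The RNAi log2 fold change was above 0 in 1457 of the 2391 rising genes, against 835 to 957 of 2298 to 2435 in the simulated sets, and in 1591 of the 2751 falling genes, against 1732 to 1901 of 3050 to 3197. With the controls split, the medians averaged 0.083 (0.054 to 0.122) and -0.050 (-0.125 to 0.022), and the SD between the RNAi libraries was 0.064 and 0.318. The covariance of both fold changes was -0.076, against -0.060 simulated. On the position scale, DjTcf4 RNAi 5 dpa libraries differed from control by 0.051 for rising genes (two-sided exact permutation p = 0.486, n = 4 and 3) and by -0.052 for falling genes (exact permutation p = 0.571). In intact animals the differences were 0.257 and 0.337 (exact permutation p = 0.2 for both, n = 4 each). Without DjTcf4 RNAi intact replicate 2 both differences were 0.103 (exact permutation p = 0.371, n = 4 and 3), a setting added after the data were seen. Over these 4 tests the adjusted p was 0.4 for both intact differences and 0.571 for both at 5 dpa, and the smallest p the design allows is 0.0286. The genes and the scale came from the control libraries under comparison, so RNAi and control labels were not exchangeable. With no RNAi effect, RNAi libraries would tend to lie inward of the control means. These permutation p-values are therefore approximate.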

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

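The tests of explanations in this part were chosen after the results were seen. DjTcf4 RNAi intact replicate 2 had 398 genes at least 1.5-fold below every other library, against 2 to 17 in the other 3 libraries of its group, and 98 genes above every other library. The table argues against 2 explanations. On the rising genes the 5 dpa libraries stood at 0.914 or more (SD 0.082), while this library stood at 0.717. That argues against a 5 dpa library of these groups under an intact label. A further 5 dpa library could lie below the lowest seen, however, and on the falling genes this library stood at 1.04. In this library DJKW.14394 stood at 240 CPM, against 49.3 to 56.4 CPM in the DjTcf4 RNAi 5 dpa libraries. It had DJKW.51 at 15.9 CPM, against 51.1 to 61.4 CPM in the control 5 dpa libraries. Together these 2 genes argue against a library of either 5 dpa group, though both were picked by their RNAi calls. A mixture of intact and 5 dpa RNA would give 1 fraction for rising and falling genes, while the median fractions were 0.519 and 1.08, a difference of 0.563 with an SD of 0.215 in the other RNAi libraries. RNA quality and the tissue taken cannot be told apart for the 398 genes, since no value in the table measures either, and a fragment of another time stays open too; no biological explanation was tested.

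Control 5 dpa replicate 2 lay apart from its group in 4 values. It had 19888 genes with a count, against 21465 to 21650 in the other 3 libraries, and the smallest total, 8136366 counts. It had 22 genes above every other library, against 0 to 1, and 57 below, against 1 to 9. DJKW.832 stood at 6.69 CPM there, against 8.09 to 8.25 CPM. In control 5 dpa replicate 4, DJKW.14394 stood at 223 CPM, against 180 to 185 CPM in the other 3. Chance marks about 1 in 20 groups of 4 in this way, and 33 group values were examined, several of them related.

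The response of DJKW.14394 to DjTcf4 RNAi differed between intact and 5 dpa animals by a log2 fold change of -1.23 in the interaction test.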

How the results depend on the processing

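Values without DjTcf4 RNAi intact replicate 2 for RNAi at 5 dpa and control regeneration, and every alternative for the regeneration correlation, were chosen after the data were seen. The cause of a difference was not tested except where fewer libraries or a fold threshold make it. The log2 fold changes followed for DJKW.51, DJKW.14394 and DJKW.832 kept their sign in every alternative. The sign of other called genes was not followed. Correlations and medians near 0 changed sign, as given below. For RNAi in intact animals (2 calls), DESeq2 size factors, library size alone and no filter each gave 4, the replicate block 1, DESeq2 36, limma-voom 43, the compared groups alone 1 and the fold threshold 1; leaving out a library gave 1 to 23. For RNAi at 5 dpa (8), no filter gave 17, the replicate block 4, DESeq2 40, limma-voom 56 and the compared groups alone 16; leaving out a library gave 4 to 28. For regeneration in control (5142), limma-voom gave 8089 and the fold threshold 1915; leaving out a library gave 2950 to 6965. For regeneration in DjTcf4 RNAi (2305), limma-voom gave 6962, the compared groups alone 575 and the fold threshold 779; leaving out a library gave 1048 to 6196. For the interaction (1), library size alone and no filter gave 3 each, the replicate block 0, DESeq2 9 and limma-voom 4; leaving out a library gave 0 to 3. The correlation of the RNAi responses (0.027) was 0.801 over genes called in either comparison, a set chosen on those calls, and -0.055 to 0.153 with a library left out. The regeneration correlation (0.764) was 0.278 with no filter and 0.677 to 0.831 with a library left out. The median RNAi response of regeneration genes moved from its value with all libraries by less than the SD between RNAi libraries (0.064 rising, 0.318 falling) in all 20 alternatives for each direction. That SD is between single libraries, so leaving out 1 library could hardly move the median by as much. The median lay between 0.0046 and 0.0895 for rising genes and between -0.137 and 0.229 for falling genes (0.058 with all libraries). For falling genes it changed sign without DjTcf4 RNAi 5 dpa replicate 1 (-0.137), with split controls (-0.050) and with the replicate block (-0.00083). With the replicate block DJKW.14394 had an interaction adjusted p of 0.164 and DJKW.832 an adjusted p of 0.23 at 5 dpa. Same-numbered libraries did not deviate together (correlations from -0.33 to 0.21), and 0 of 15 correlated best with their own number, so the numbers were not taken as pairs. The depth (8136366 to 12224216 counts) and this spread recovered 13.4% and 8.96% of simulated 1.5-fold RNAi changes in intact and 5 dpa animals, so absent calls do not exclude changes of that size.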

Other observations

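The tests of explanations in this part, and the thresholds for the counts of splits, were written down after the results were seen. The genes lower with DjTcf4 RNAi at 5 dpa were mostly also lower after amputation in control, 22 of 25 without DjTcf4 RNAi intact replicate 2. The falling genes as a set did not move by about the -0.98 of the called genes. The set's median lay no farther from 0 than 0.152 in any split of the controls, with an SD of 0.318 between RNAi libraries. The called genes were picked by their RNAi change in these same libraries. Their -0.98 therefore overstates what a general shift along the change after amputation would need. The rising genes had a median above 0 in each of these splits (0.032 to 0.118), the direction of such a shift. A small shift stays open, but not a shift of the whole set by -0.98. Whether a small shift explains the calls cannot be decided by this test. A candidate explanation left open is that a small set of genes that falls after amputation is also lower with DjTcf4 RNAi, in intact animals as well as at 5 dpa. Without DjTcf4 RNAi intact replicate 2, the 25 genes had a median log2 fold change of -0.52 with RNAi in intact animals, and 24 were below 0. An interaction was called for only 3 genes in that setting. The candidate was found and tested on the same libraries, and the genes have no names here.

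Falls of at least 2-fold outnumbered rises after amputation in control, 1724 to 191. The choice among the scalings used did not make this excess, since the lowest ratio of falls to rises under the other scalings was 10.03 (9.03 with TMM). These scalings differed little, however. The median log2 fold change over all genes was 0.036 with TMM, 0.0075 with DESeq2 size factors and -0.037 with library size alone. A scaling error common to them was not tested, so scaling stays open. Low counts are argued against, because the ratio was 10.6 in the 4274 genes with the highest expression. Falls outnumbered rises less, 42 to 9, in the 1000 most abundant. Whether the falls reflect tissue missing from trunk fragments cannot be told apart from a response to amputation, because every 5 dpa library is a trunk fragment. DjTcf4 RNAi intact replicate 2, labelled intact, lay past the midpoint towards 5 dpa for 88.9% of the falling genes (3.13% to 7.89% in the other libraries of its group). It did so for 63.9% of the 191 rising genes too, but its own place is in doubt.

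Other splits of the same libraries into groups of the same sizes, each fitted to the compared groups alone, were counted with the real one included. For 5 dpa against intact controls, 1 of 35 splits gave as many calls as the real 6606, with 1 as the highest other. That argues against chance for this count, though 35 splits allow no share below 1 in 35. The splits alone do not argue against chance for the counts of the other comparisons. For RNAi in intact animals, 2 of 35 splits gave as many as the real 1, and the highest other, 38, set control replicates 2, 3 and 4 with RNAi replicate 3, which points to a structure of the samples. Those 4 libraries had 20699 to 21396 genes with a count and 6.93% to 7.90% fractional values. The other 4 had 22007 to 22878 and 8.89% to 10.2%. Both sets also differed on the first principal component, at -69.2 to -49.7 against -37.2 to 55.9. Their positions on the genes lower at 5 dpa were -0.146 to 0.031 against 0.158 to 1.04. The cause was not tested. For RNAi at 5 dpa, 3 of 35 splits reached the real 16, and the highest other, 70, set control replicates 2 and 3 with RNAi replicate 1, which again points to an untested structure. For 5 dpa against intact DjTcf4 RNAi animals, 3 of 35 reached the real 575, and the highest other, 3798, set intact replicate 2 with the 5 dpa libraries. Chance is argued against for these calls as a set by their overlap with the control response, which shares no library with them. There were 947 genes higher in both where 163 were expected, and 804 lower in both where 184 were expected. Both lists come from 1 fit with a shared spread per gene, so these expected numbers may be too low. A shared spread would raise overlaps in opposite directions too, where 0 genes were found against 160 and 187 expected. For DJKW.51 chance is argued against by its call in both RNAi comparisons, where 0.00082 shared genes were expected under the same limit. For the interaction, 5 of 40 drawn splits reached the real 1, with 4 as the highest other.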
